A study of Arabidopsis thaliana with 21 samples.

How the data were processed

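The series holds ChIP-seq of 21 samples in 7 groups of 3, labelled as biological replicates: H3 and H3K27me3 ChIP from Col plants, input and FIE ChIP from C24 plants carrying HA-tagged FIE, and input, AZF1 ChIP and BPC1 ChIP from Col plants carrying Myc-tagged proteins. The Col input came from the AZF1-Myc line, per the labels. Per the submitters' processing notes the tools were Bowtie2, bedtools and MACS2 2.1.1.20160309, and the genome build was TAIR10. The settings of the aligner and the caller are not given in the sources used here. The 4 lists carry no replicate column and were taken as pooled over replicates; how replicates were combined is not given in the sources used here. The series design names the Col input for AZF1 and BPC1, the C24 input for FIE and H3 for H3K27me3, and the lists themselves do not name their controls. Each list was filtered after calling, since its peak numbers have gaps and its lowest −log10 q is 10.

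In the deposited lists, column 7 is the fold enrichment of a region over its control, a ratio in the layout of MACS2. The authors' files also give −log10 p and −log10 q per region, and a score that equals 10 times −log10 q cut to a whole number in 100% of rows. The narrow lists (FIE, AZF1, BPC1) add the position of the summit, and for H3K27me3 the midpoint of a region was used in its place. The per-region values are the authors'; they carry no replicate error, and ranks between lists of different lengths show no change. The lists give no read counts, so depth per sample is unknown and intervals on shares cover counting error over regions only. Tests of AZF1 against BPC1 regions treat the lists as independent, although regions in both lists count on both sides. Regions can lie near each other and are not independent replicates, so Fisher p-values are too small where regions cluster. The same holds for tests of gene lists and families where members lie side by side, as neighbouring genes can be assigned through the same region.

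From these lists, regions on the 5 nuclear chromosomes were compared, and regions on the organelle genomes were left out. Coordinates are 1-based and on TAIR10. The planned placement of regions by transcription start could not be run, because the gene table used has no strand, and no genome sequence was used here. The stated fallback was applied: each list was rotated 1000 times along each chromosome, an overlap counted from 1 bp, and a two-sided p was taken from the placements, with Benjamini-Hochberg adjustment over 6 overlaps. The smallest p this allows is 0.0020. Shares were compared with two-sided Fisher's exact tests, adjusted over 6 tests, with Woolf intervals for odds ratios and 95% Wilson intervals for shares. Median fold enrichments were compared with a permutation test of 100000 resamples. For the same reason, 11 planned motif tests and the 6-mer search were not run.

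Gene names came from a RefSeq table of the TAIR10.1 assembly, with 37899 nuclear genes, of which 27444 are protein-coding. The nuclear chromosomes of TAIR10.1 were taken to be numbered as in TAIR10. This was checked on the lists: shifting the summits of chromosome arms by up to 2 kb gave the highest share inside genes at no shift on all 5 chromosomes for each narrow list. At shifts of 20000 bp the FIE share over all arms was 60.8% and 60.5%, above the 58.7% at no shift, so for FIE the check holds only over the short range; the AZF1 and BPC1 shares stayed below theirs at no shift. No gene coordinate is printed. A gene was assigned to a narrow list when a summit lay within the gene extended by 1 kb at both ends, and to the broad H3K27me3 list when a region touched the extended gene; extending both ends replaced the planned upstream side alone. UTRs, exons and introns were not used here. Of 19 gene lists fixed, 18 were tested against all other protein-coding genes (tRNA genes against all nuclear genes) in 5 sets, FIE, AZF1, BPC1, H3K27me3 and all 4 together, with adjustment over 90 tests; the list of transposable element genes was not analysed here. Of 313 members written in the named lists, 305 were matched by symbol or synonym, 8 of them by hand. The lists tested were those of PRC2 core, PRC2-linked and PRC1-like, BPC family, AZF and ZAT zinc finger, MADS-box floral identity, flowering time, meristem and organ identity, root and stem cell, embryo and seed maturation, seed storage and late embryo, gibberellin and abscisic acid metabolism, auxin synthesis and transport, stress response, photosynthesis, housekeeping, ribosomal protein, tRNA and core histone genes.

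Named genes followed a rule: members of the MADS-box, flowering time, meristem, embryo and seed maturation, BPC and zinc finger lists; the genes at the 5 regions of highest fold in each narrow list; those at the 5 H3K27me3 regions of highest fold and at least 1 kb; and the genes nearest to the 10 FIE regions of highest fold that met all other lists. This rule, the groups, the tests, the gene lists and the following other settings were chosen before the data were examined. These settings were an overlap of at least 50% of the first region, only regions above the median −log10 q, only the first 1000 regions of each list, genes extended by 500 bp or 2 kb, FIE regions inside H3K27me3 only, and leaving out regions in both factor lists. Added after seeing the data were placements matched on the nearest gene, chromosome arms only (without 15 windows of 1 Mb holding fewer than 100 protein-coding genes and without 3 to 4 Mb of chromosome 2), regions cut to 100 bp each side of the summit, FIE regions up to the median width, gene bodies only, and 10 strata of gene length (Mantel-Haenszel test). The quintiles of FIE fold and the shares of FIE at AZF1 regions with and without BPC1, and at BPC1 regions with and without AZF1, were likewise added after seeing the data.

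The functions were tested on simulated data. For AZF1 at FIE over 4464 regions, 100 randomly rotated lists gave a median ratio of 0.968 to their placements and 6 of them passed a p of 0.05. With 30% of the regions moved onto FIE regions, the median recovered was 30.0% and all 100 lists passed. Over 27444 genes, 0 of 100 random gene lists passed against FIE genes after adjustment, and 100 of 100 did with 10 members drawn from FIE genes. For FIE fold over 5006 regions, a planted difference of 1 in the median came back as a median of 0.999. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.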

Results

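Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Arabidopsis thaliana plants aged 30 h and grown with 16 h of light and 8 h of dark per day. The proteins profiled were FIE, AZF1 and BPC1. FIE (FERTILIZATION INDEPENDENT ENDOSPERM) is a WD40 subunit of Polycomb repressive complex 2 (PRC2), which places trimethylation on lysine 27 of histone H3 (H3K27me3). AZF1 is a C2H2 zinc finger protein, and BPC1 belongs to the BASIC PENTACYSTEINE family, whose members bind GA repeats. H3K27me3 was profiled beside them. The 21 samples fell into 7 groups of 3: ChIP of FIE, AZF1, BPC1, H3K27me3 and total histone H3, and input chromatin from C24 and from Col plants. FIE was precipitated through an HA tag in the C24 accession, and AZF1 and BPC1 through Myc tags in Col. H3K27me3 and H3 were profiled in Col as well, so each comparison of FIE with the mark or the factors is between accessions. The deposited data were 4 lists of enriched regions, 1 per protein or mark, with no values for single replicates, so no spread between replicates could be given. Each fold enrichment below is the authors' value for that region over its control and is compared only within its own list. The lists carry no read counts, so the depth behind a region is unknown.

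On the 5 nuclear chromosomes the lists held 5006 FIE, 4464 AZF1, 2622 BPC1 and 3940 H3K27me3 regions. Median widths were 267 bp for FIE, 144 bp for AZF1 and 157 bp for BPC1. H3K27me3 regions had a median width of 2980.5 bp and together covered 15272 kb, or 12.8% of the nuclear chromosomes. Regions were unevenly spread. The 15 windows of 1 Mb with fewer than 100 protein-coding genes held 40.3% of AZF1, 29.9% of FIE and 22.9% of BPC1 regions but 7.23% of H3K27me3 regions. A single window of chromosome 2, from 3 to 4 Mb, held 360 BPC1 regions. The term chromosome arms is used below for the nuclear genome without these windows, which left 3455 FIE, 2544 AZF1, 1661 BPC1 and 3643 H3K27me3 regions.

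**Figure D1:**
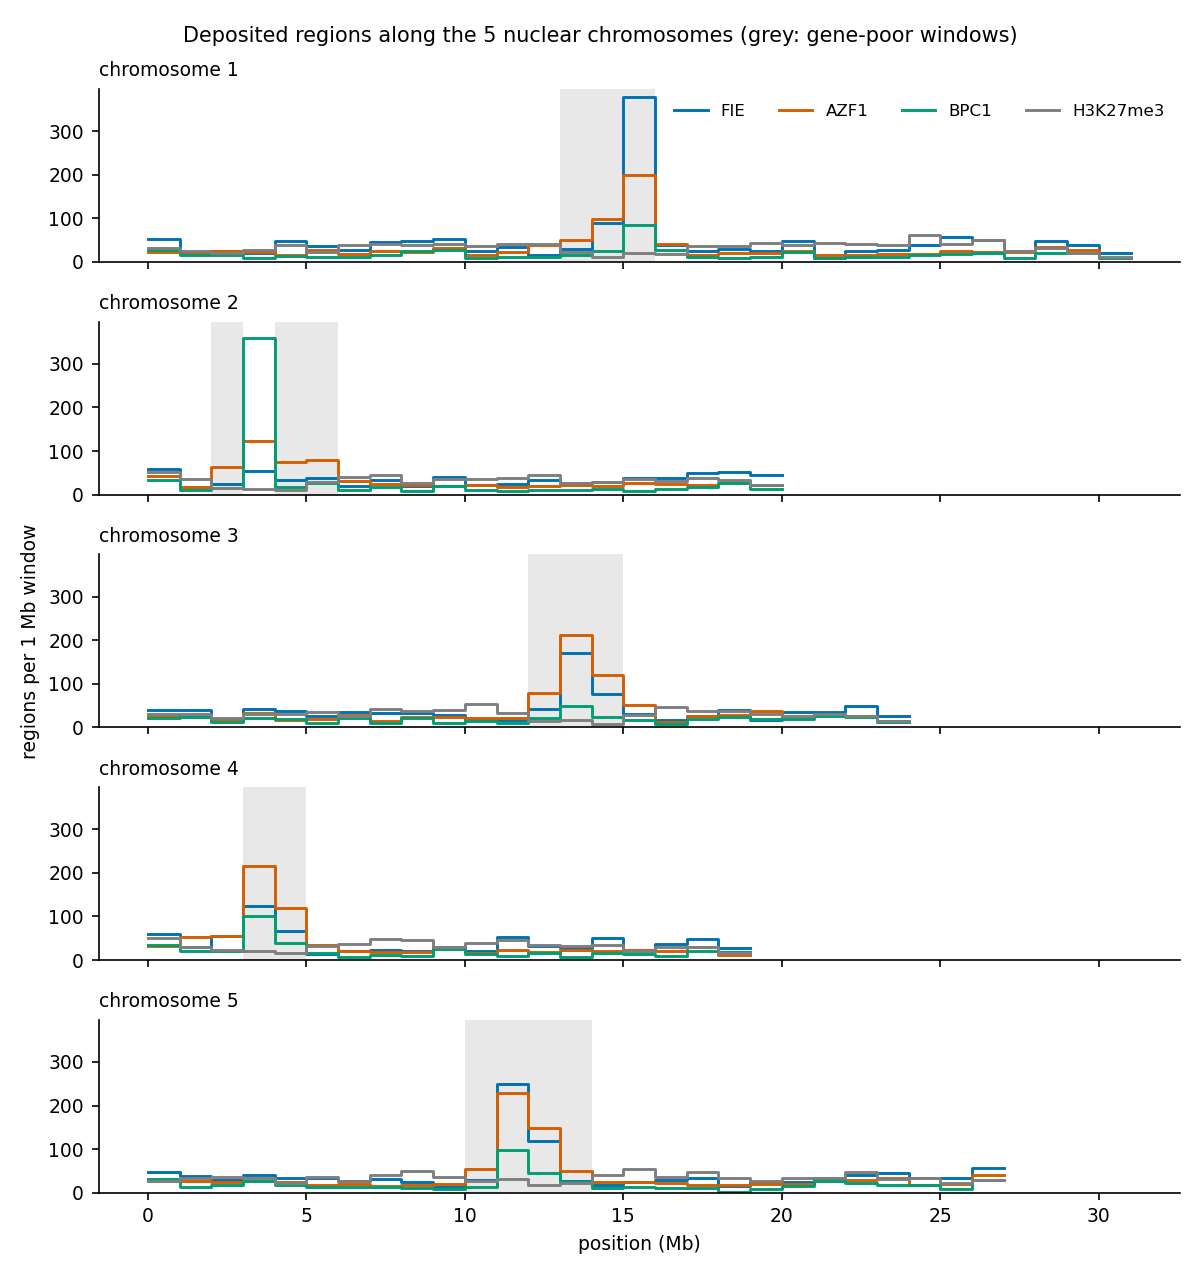
Number of deposited regions (vertical axis) in each 1 Mb window along the 5 nuclear chromosomes (horizontal axis, Mb), with 1 line per list and gene-poor windows shaded grey. The FIE, AZF1 and BPC1 lines peak in some of the gene-poor windows, and BPC1 reaches 360 regions between 3 and 4 Mb of chromosome 2.

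The first comparison asked how far FIE occupancy coincided with the mark that PRC2 places. Of 5006 FIE regions, 2490 (49.7%, 95% Wilson interval 48.4 to 51.1) overlapped an H3K27me3 region. In 1000 rotations of the FIE list along the chromosomes the mean was 14.2%, so the observed share was 3.50-fold higher (adjusted permutation p = 0.0020, two-sided, the smallest that the placements can give). In the other direction, 33.3% of H3K27me3 regions held a FIE region. The strongest FIE regions were at EMF1, which encodes a Polycomb-associated protein, with a fold enrichment of 26.8 (chromosome 5, 3693927 to 3697668), and the floral homeotic gene AGAMOUS (AG) with 25.5 (chromosome 4, 10385729 to 10387137). Next came AT3G06435 with 23.6 (chromosome 3, 1969663 to 1971051), ROS3 with 20.2 (chromosome 5, 23522565 to 23523904) and an intergenic region whose nearest gene was the meristem gene STM with 17.7 (chromosome 1, 23065563 to 23066768). Of these 5 regions, only the one in ROS3 did not overlap H3K27me3. On chromosome arms the share of FIE regions in H3K27me3 was 65.1%, against 15.3% in gene-poor windows.

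AZF1 and BPC1 regions lay at FIE regions far more often than rotated lists did, BPC1 more so than AZF1. Of 2622 BPC1 regions, 1391 (53.1%, interval 51.1 to 54.96) overlapped FIE against 2.66% after rotation, a 19.97-fold difference. Of 4464 AZF1 regions, 1493 (33.4%, 32.1 to 34.8) did so against 2.52%, a 13.3-fold difference. Both overlaps exceeded every placement (adjusted permutation p = 0.0020, the smallest possible). The odds of lying at FIE were lower for AZF1 than for BPC1 regions, with an odds ratio of 0.445 (95% interval 0.403 to 0.491, Fisher's exact test, two-sided, adjusted p = 1.19e-58). On chromosome arms the shares were 25.1% for AZF1 and 56.8% for BPC1, with an odds ratio of 0.254. Over all nuclear regions without those in both factor lists, the odds ratio was 0.326. The strongest BPC1 regions were at EMF1 (fold 11.8), AG (8.92), PETAL LOSS (PTL; 8.77), AT3G06435 (8.12) and AT2G03040 (7.01), and all 5 overlapped FIE, AZF1 and H3K27me3. The strongest AZF1 region, with a fold of 5.83, lay inside EIR1 (also PIN2), a gene of root auxin efflux (chromosome 5, 23102917 to 23103026). The next by fold (5.73), nearest to AT5G67460, overlapped the AZF1 gene itself and no FIE, BPC1 or H3K27me3 region. These plants carried Myc-tagged AZF1, so signal from that copy cannot be told apart from binding at the gene. Then came EMF1 with 5.64, FBA6, an aldolase gene, with 5.59, and an intergenic region near AT4G03740 with 5.51. The FBA6 region overlapped BPC1 and neither FIE nor H3K27me3.

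**Figure D2:**
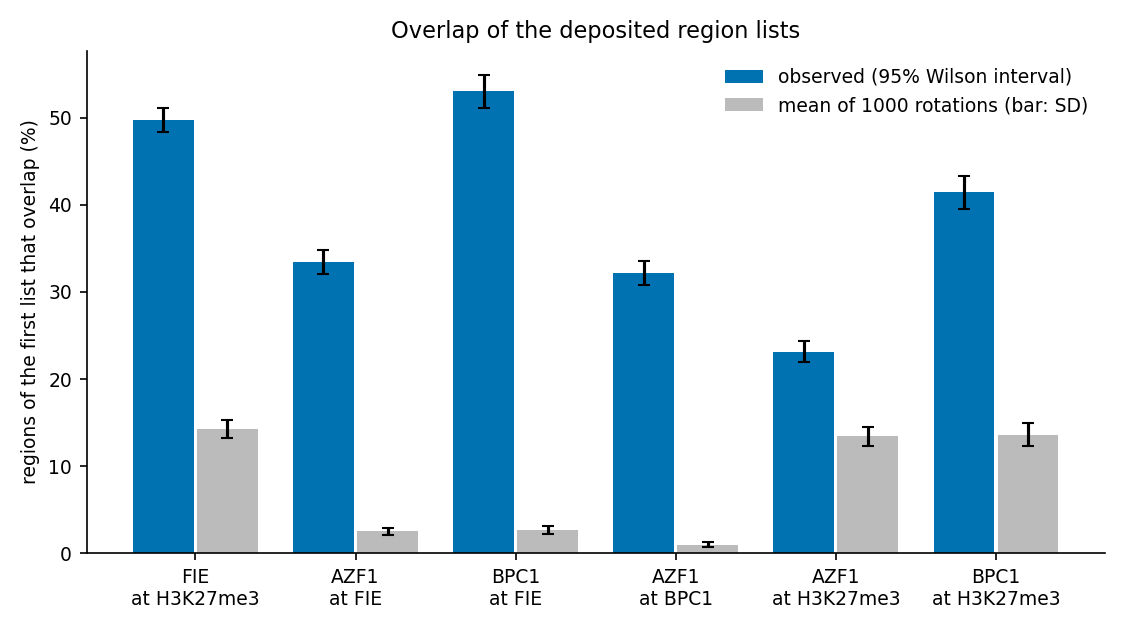
Share of regions of the first list that overlap the second by at least 1 bp (vertical axis, %), for the 6 pairs of lists, with 95% Wilson intervals, beside the mean and SD of 1000 rotations. Observed shares range from 23.1% for AZF1 in H3K27me3 to 53.1% for BPC1 at FIE, and each lies above its rotated mean.

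Regions of the factors also coincided with each other. Of 4464 AZF1 regions, 1436 (32.2%, interval 30.8 to 33.6) overlapped a BPC1 region against 0.990% after rotation, a 32.5-fold difference (adjusted permutation p = 0.0020, the smallest possible), and 55.6% of BPC1 regions overlapped AZF1. By gene, 947 of the 2711 AZF1 genes and 1610 BPC1 genes were shared, where independent sets of these sizes would share 159. Among FIE regions, 54.9% of those with AZF1 also had BPC1, against 11.3% of those without AZF1 (odds ratio 9.52, interval 8.22 to 11.04, Fisher's exact test, adjusted p = 1.05e-214). AZF1 regions shared with BPC1 were at FIE in 57.9% of cases and other AZF1 regions in 21.8% (odds ratio 4.93, interval 4.31 to 5.65). For BPC1 regions the corresponding shares were 58.6% with AZF1 and 46.1% without (odds ratio 1.65), but this order turned on chromosome arms, where they were 51.5% and 62.7% (odds ratio 0.631, interval 0.519 to 0.768). AZF1 and BPC1 share the Col input in the series design, though the lists do not name their controls, and were precipitated through the same kind of tag, so part of their overlap may come from shared controls, whose effect on these counts could not be simulated without reads.

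BPC1 regions lay in H3K27me3 more often than AZF1 regions. The shares were 41.5% (interval 39.6 to 43.4) for BPC1 against 13.6% after rotation, and 23.1% (21.9 to 24.4) for AZF1 against 13.4%, which are 3.05-fold and 1.72-fold differences (adjusted permutation p = 0.0020 for both, the smallest possible). The odds ratio of AZF1 over BPC1 was 0.425 (interval 0.383 to 0.472, Fisher's exact test, adjusted p = 3.59e-58). Without regions in both factor lists it was 0.231. Inside H3K27me3, 79.9% of BPC1 regions were at FIE against 34.1% outside (odds ratio 7.67, interval 6.39 to 9.20, Fisher's exact test, adjusted p = 1.29e-123). For AZF1 the shares were 55.2% and 26.9% (odds ratio 3.35, interval 2.90 to 3.86, Fisher's exact test, adjusted p = 5.06e-61).

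FIE regions with different factors differed in the mark. FIE regions with BPC1 and without AZF1 overlapped H3K27me3 in 78.0% of 409 cases (interval 73.7 to 81.7), and those with AZF1 and without BPC1 in 23.4% of 629 (20.2 to 26.8). FIE regions with neither factor did so in 51.8% of 3203 and those with both in 47.8% of 765. The last pair, which was the planned test, did not differ past the threshold (odds ratio 0.855, interval 0.730 to 1.00, Fisher's exact test, adjusted p = 0.0534). On chromosome arms the shares were 81.4% with BPC1 alone, 43.1% with AZF1 alone, 64.1% with neither and 65.9% with both. With at least 50% of the FIE region required to be covered, the test of both against neither passed (odds ratio 0.501, Fisher's exact test, adjusted p = 1.11e-11).

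**Figure D3:**
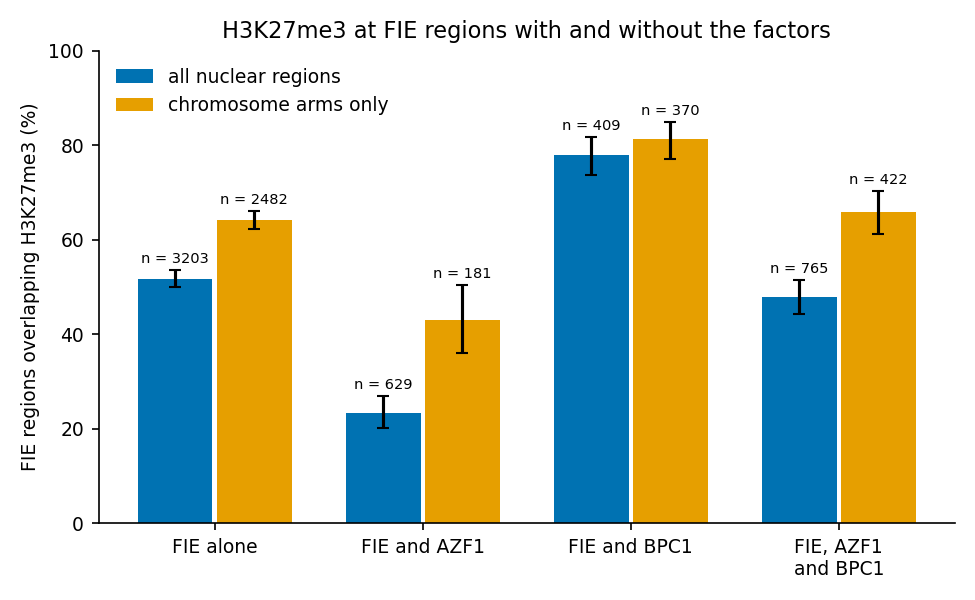
Share of FIE regions overlapping H3K27me3 (vertical axis, %) for FIE regions without either factor, with AZF1 only, with BPC1 only and with both, over all nuclear regions and over chromosome arms, with 95% Wilson intervals and the number of regions. The class with BPC1 only is highest at 78.0% and 81.4%, and the class with AZF1 only is lowest at 23.4% and 43.1%.

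The height of FIE regions was then set against the presence of the factors. FIE regions with AZF1 or BPC1 had a median fold enrichment of 4.84 (n = 1803) against 4.65 for those with neither (n = 3203), a difference of 0.195 (permutation test with 100000 resamples, p = 1e-05, the smallest they can give). FIE regions with BPC1 only had a median of 6.36, those with both factors 4.83 and those with AZF1 only 4.30. In the highest quintile of FIE regions by fold enrichment, 46.8% overlapped BPC1 and 69.4% H3K27me3, against 21.6% and 33.9% in the lowest quintile. AZF1 was met by 33.2% of the highest and 39.5% of the lowest quintile. The middle quintile lay below both ends for the factors, with 14.3% for BPC1 and 20.8% for AZF1. High FIE regions were also wider, with a median of 581 bp against 212 bp, and among FIE regions no wider than the overall median of 267 bp the difference in median fold turned to -0.291. It was 1.03 among FIE regions inside H3K27me3 and 0.746 on chromosome arms.

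**Figure D4:**
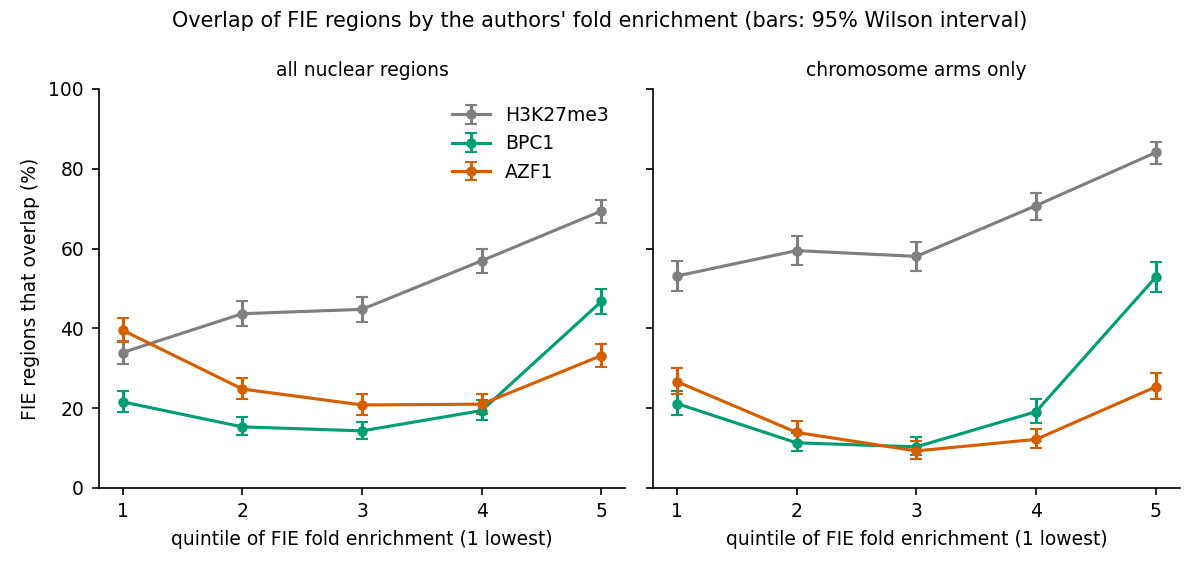
Share of FIE regions that overlap H3K27me3, BPC1 and AZF1 (vertical axis, %) by quintile of the authors' FIE fold enrichment (horizontal axis, 1 lowest), over all nuclear regions and over chromosome arms, with 95% Wilson intervals. BPC1 overlap is 46.8% in the highest quintile over all regions and 52.8% on chromosome arms.

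Which genes carried the regions was asked with gene lists fixed in advance. A gene was assigned to a narrow list when a summit lay within the gene or 1 kb of it, and to H3K27me3 when a region did. Of 27444 protein-coding genes, 2560 were assigned to FIE, 2711 to AZF1, 1610 to BPC1, 7492 to H3K27me3 and 311 (1.13%) to all 4 lists. FIE and H3K27me3 shared 1696 genes, where independent sets would share 699.

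Floral and meristem regulators stood out in all 4 lists. Of 23 MADS-box floral identity genes, 21 were assigned to FIE against 9.26% of other genes, 18 to BPC1, 10 to AZF1 and 22 to H3K27me3 (Fisher's exact test, adjusted p = 1.36e-18, 3.53e-17, 0.000205 and 5.89e-11). The 10 in AZF1 were those in all 4 lists: AG, APETALA1 (AP1), AP3, SEP1, SEP2, STK, AGL8 (FRUITFULL), SVP, AGL20 (SOC1) and AGL12. Membership is by gene, so regions of a gene in all 4 lists need not overlap. At AP3 the AZF1 region (chromosome 3, 20119494 to 20119593) lay apart from the FIE region (20120176 to 20121666). That AZF1 region was also the one assigned to WRI1, counted among the embryo and seed maturation regulators. At AP1 the highest FIE region had a fold of 15.3 (chromosome 1, 25984499 to 25987252), with AZF1 at 3.55 and BPC1 at 4.89, and the H3K27me3 region was 12025 bp wide. At SVP, a repressor of flowering, the values were 12.7 for FIE, 2.94 for AZF1 and 5.29 for BPC1. AGL17 and AGL19 had H3K27me3 but no assigned FIE region, and SEP4 had FIE without H3K27me3. Of 41 meristem and organ identity genes, 35 were assigned to FIE, 25 to BPC1, 20 to AZF1 and 35 to H3K27me3 (Fisher's exact test, adjusted p = 1.63e-28, 2.52e-19, 1.94e-09 and 2.23e-13), and 12 to all 4. These 12 included STM (FIE fold 14.2), the boundary gene CUC2 (10.1) and the leaf genes BOP1 (13.9), JAG (13.8) and NUB (8.26). The polarity genes AFO (10.5), YAB3 (15.3), KAN (12.1) and KAN2 (8.93) were also among them. The lowest FIE folds of the 12 were at WOX1 (7.15), HB-3 (6.41) and CUC3 (5.46). The stem cell gene WUS had FIE (8.87), BPC1 (3.71) and H3K27me3 without AZF1, while CLV3 had AZF1 (3.04) and H3K27me3 without FIE. REV was in none of the lists.

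Smaller shares of seed, root and auxin genes were assigned. Of 16 embryo and seed maturation regulators, 6 were assigned to FIE, 6 to AZF1 and 4 to BPC1 (Fisher's exact test, adjusted p = 0.0104, 0.0132 and 0.0456), and LEC2 and FUS3 were in all 4 lists with FIE folds of 9.03 and 10.03. LEC1 was in none, and ABI5 had AZF1 (4.85), BPC1 (4.25) and H3K27me3 without FIE. H3K27me3 with 7 did not pass (Fisher's exact test, adjusted p = 0.358). The AZF1 call was lost with genes extended by 500 bp, with gene bodies and with regions above the median −log10 q. Of 14 root and stem cell factors, 7 were assigned to FIE and 5 to BPC1 (Fisher's exact test, adjusted p = 0.000745 and 0.00468), and 2 to all 4, the root genes PLT2 and SMB, named after their values were seen. AZF1 with 4 and H3K27me3 with 8 did not pass (Fisher's exact test, adjusted p = 0.123 and 0.0880), but H3K27me3 passed with genes extended by 500 bp and with gene bodies, where AZF1 passed too. The overlap with all 4 lists was not past the threshold with genes extended by 2 kb or with regions above the median −log10 q. Of 27 auxin synthesis and transport genes, 9 were assigned to FIE, 6 to BPC1 and 7 to AZF1 (Fisher's exact test, adjusted p = 0.00293, 0.0168 and 0.0479), and 4 to all 4 lists: YUC1, TAA1, EIR1 and AUX1, of which the others than EIR1 were named after their values were seen. H3K27me3 with 13 did not pass (Fisher's exact test, adjusted p = 0.0859), but did with genes extended by 500 bp, with gene bodies and in strata of gene length. For the auxin genes the AZF1 call was lost with genes extended by 2 kb, with regions above the median −log10 q and in strata of gene length, the BPC1 call with gene bodies, and the call for all 4 lists with regions above the median −log10 q. Of 21 seed storage and late embryo protein genes, 7 were assigned to FIE (Fisher's exact test, adjusted p = 0.0104), without a call for the other lists, and this call was lost with regions above the median −log10 q and with gene bodies. The 7 include the neighbouring genes SESA1, SESA3 and SESA4, named after their values were seen, which the test counts as independent.

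Of the remaining lists, only tRNA genes passed the threshold in any set. Of 28 flowering time genes, 4 were assigned to FIE and 7 to H3K27me3 (Fisher's exact test, adjusted p = 0.612 and 1). Some regulators of flowering, such as the repressor SVP, were counted in the MADS-box floral identity list instead. The contrast between these lists thus depends in part on how they were split. FT, TSF, TFL1 and CO carried H3K27me3 without FIE, and LFY had FIE (8.00) with H3K27me3. FLC and MAF1 to MAF5 were in none of the 4 lists, which hold only regions with a −log10 q of at least 10. Of 25 gibberellin and abscisic acid metabolism genes, 6 were assigned to FIE, and of 22 stress response genes 5 (Fisher's exact test, adjusted p = 0.0820 and 0.136), of which the gibberellin and abscisic acid list passed for FIE with genes extended by 500 bp. FIE was assigned to 0 of 26 photosynthesis genes, 0 of 24 housekeeping genes, 1 of 49 ribosomal protein genes and 1 of 22 core histone genes (Fisher's exact test, adjusted p = 0.358, 0.358, 0.225 and 0.980). AZF1 was assigned to 6 of the 24 housekeeping genes (Fisher's exact test, adjusted p = 0.0841), which passed with genes extended by 500 bp and with gene bodies. Of the 8 PRC2 core genes 0 were assigned to FIE and 3 to H3K27me3, and of 15 PRC2-linked and PRC1-like genes 2 were assigned to FIE, EMF1 and the vernalization gene VIN3, the latter named after its values were seen. The BPC family had 1 of 7 members in the BPC1 list, BPC1 itself (fold 2.29), and 1 in the FIE list, BPC2 (6.63). The region of BPC1 lay within 1 kb of the gene without overlapping it. Its fold was below 2.52, the lower quartile of nuclear BPC1 regions. These plants carried Myc-tagged BPC1, so signal from that copy cannot be told apart from binding near the gene. Among 8 zinc finger genes of the AZF and ZAT class, 1 was assigned to AZF1, RHL41 (ZAT12; 3.85). None of these families passed the threshold. Of 625 tRNA genes, 19 were assigned to FIE and 20 to AZF1, below the 9.66% and 11.3% of other genes (Fisher's exact test, adjusted p = 1.94e-09 and 3.39e-12), though their median length is 73 bp. They were also fewer in H3K27me3, at 13.3% against 25.7% (Fisher's exact test, adjusted p = 8.8e-13), and 0 were in all 4 lists (adjusted p = 0.00556), while BPC1 had 5.12% against 6.43% (adjusted p = 0.441).

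**Figure D5:**
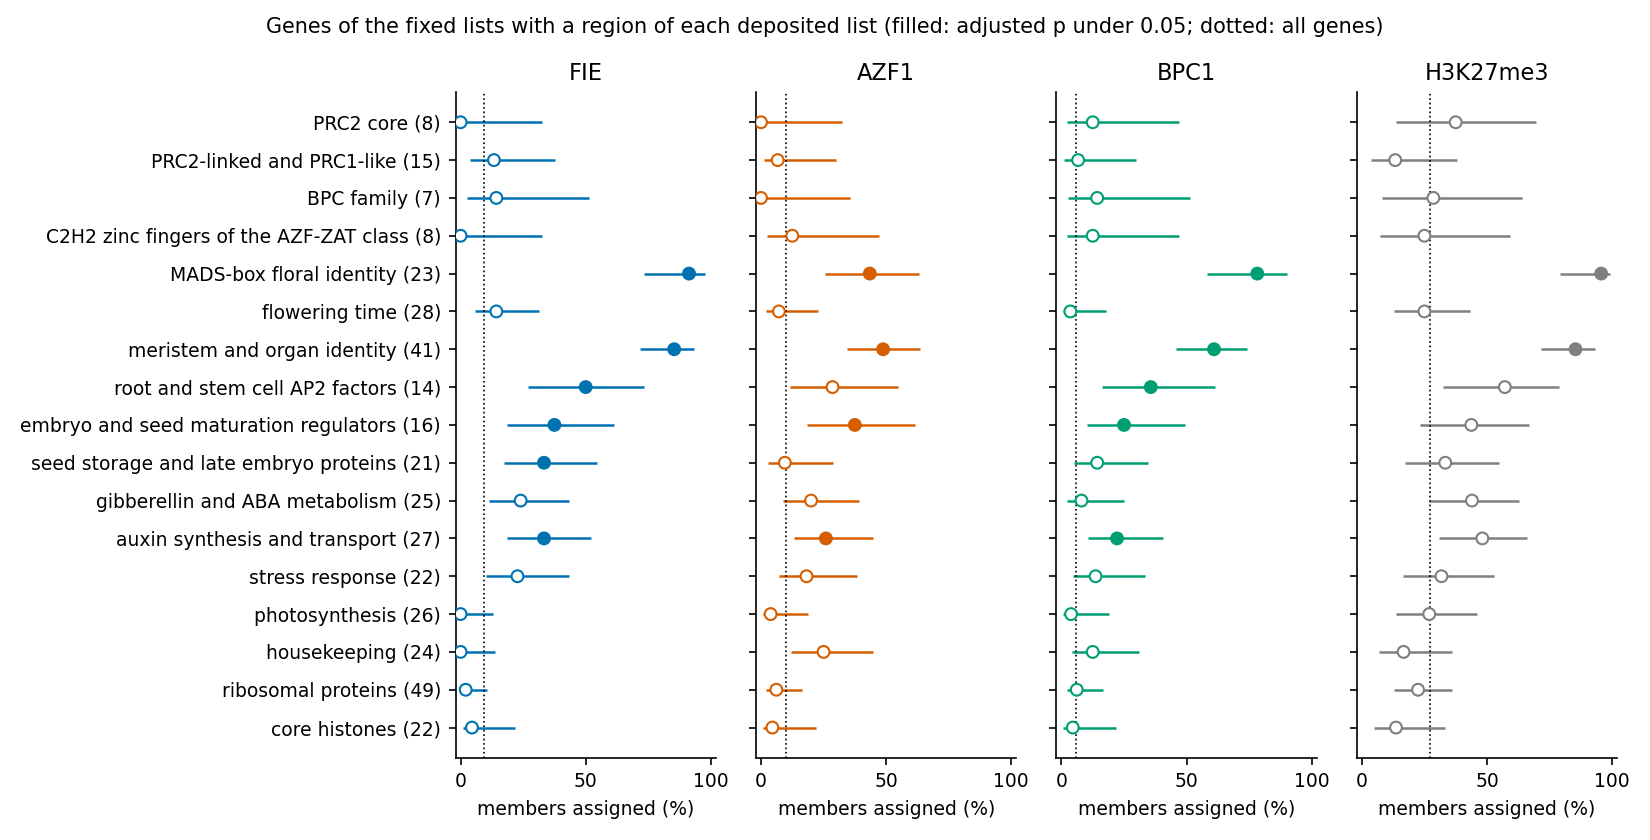
Share of the members of each gene list (rows, with the number of members) assigned to FIE, AZF1, BPC1 and H3K27me3 (horizontal axes, %), with 95% Wilson intervals; filled points passed an adjusted p of 0.05 and dotted lines give the share of all protein-coding genes. MADS-box floral identity genes reach 91.3% for FIE and 95.7% for H3K27me3.

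The regions where all lists met are described last. Of 5006 FIE regions, 366 (7.31%, interval 6.62 to 8.07) overlapped AZF1, BPC1 and H3K27me3. By FIE fold, the first 10 were at EMF1, AG, AT3G06435, AT1G53690 (17.3), near AT2G03040 (17.04), in a gene-poor stretch whose nearest gene was AT5G30520 (16.2), near AT5G06380 (16.0), in NAC067 (15.9), near the wax regulator MYB94 (15.5) and in YAB3 (15.3). The H3K27me3 regions of at least 1 kb with the highest fold were at LSH1 (4.43; chromosome 5, 10453132 to 10456358), SPL8 (4.39), AT3G58210 (4.32), AT3G28770 (4.27) and MYB92 (4.25), and each held a BPC1 region. Summits lay in a gene body in 41.6% of FIE, 41.3% of AZF1 and 50.4% of BPC1 regions, against 54.2%, 54.1% and 53.6% after rotation (permutation p = 0.0020, 0.0020 and 0.422). On chromosome arms these shares were 58.7%, 69.7% and 69.9%. No rotation was made for arms alone, but arm summits shifted by 20000 bp to either side give a comparison. The shifted shares were 60.8% and 60.5% for FIE, 58.6% and 58.8% for AZF1, and 60.7% and 62.2% for BPC1. The shortfall of AZF1 in gene bodies against rotation thus did not hold on arms, where AZF1 and BPC1 lay above their shifted shares.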

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

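All tests in this part were chosen after the results they bear on had been seen.

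BPC1 had 420 regions on the mitochondrial genome, 13.4% of its list, and 360 between 3 and 4 Mb of chromosome 2. The mitochondrial regions covered 70.7% of that genome, with a median fold of 2.25 and a highest fold of 2.96. A larger amount of mitochondrial DNA in the BPC1 precipitate than in the Col input could give this. A low mitochondrial content of the input alone is not settled by AZF1. The series design names the same Col input for it, though the lists do not name their controls. The odds of a mitochondrial region were 14.7 times higher in the BPC1 list (interval 10.9 to 19.9). Yet the Col input came from the AZF1-Myc line, so a difference in mitochondrial DNA between the plant lines cannot be told apart from one in the precipitate. The median fold of the chromosome 2 block lay within 0.0184 of the mitochondrial median, less than their SD of 0.173, whereas BPC1 regions of gene-poor windows had a median of 2.73, so reads shared between the mitochondrial genome and a copy on chromosome 2 may account for the block. No biological explanation was tested.

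Gene-poor windows held 40.3% of AZF1, 29.9% of FIE and 22.9% of BPC1 regions. Most FIE regions there lay outside the listed H3K27me3 regions: 15.3% lay in the mark, with an odds ratio of 0.0968 relative to chromosome arms (interval 0.0828 to 0.113). This does not decide on Polycomb chromatin as the source. The windows held only 7.23% of H3K27me3 regions, and the share was not set against placements inside them. FIE and the mark also came from different accessions and controls. A signal of repeat-rich DNA common to the precipitations also stays open. AZF1 regions of gene-poor windows met FIE 8.12-fold more often than at random positions inside the same windows, at 45.3% against 5.58%. On chromosome arms the same ratio was 12.7, so coincidence of the lists is not peculiar to these windows and could equally come from binding. Mapping of repeats was not tested.

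AZF1 and BPC1 regions coincided with each other, with the same kind of tag behind both and, by the series design though not named in the lists, the same input. FIE was profiled with another input, tag and accession. On chromosome arms AZF1 regions with BPC1 were at FIE with an odds ratio of 8.51 over those without (interval 6.95 to 10.4). This cannot decide on the shared input and antibody, because 56.8% of all BPC1 regions there were at FIE. In the other direction, BPC1 regions with AZF1 were at FIE less often than those without, at 51.5% against 62.7% (odds ratio 0.631). Of the 872 shared AZF1 regions on chromosome arms, 421 lay away from FIE. H3K27me3, which has H3 as its control, held 26.4% of them against 17.8% of other AZF1 regions away from FIE (odds ratio 1.66, interval 1.28 to 2.14). The same limit holds here, as these regions were chosen for overlapping BPC1. For the 310 outside the mark a shared input and antibody cannot be told apart from binding either, because no list with another control holds them. A general signal at highly transcribed genes was not settled, as 5 of 121 genes of the housekeeping, photosynthesis, ribosomal protein and core histone lists were in both sets, an odds ratio of 1.21 (interval 0.492 to 2.96). Binding of both factors at Polycomb targets stays a hypothesis, since the mark gave different answers in the 2 directions. On chromosome arms AZF1 regions with BPC1 lay in H3K27me3 with an odds ratio of 3.52 over those without (interval 2.95 to 4.21). BPC1 regions with AZF1 lay in it less often than those without, at 47.5% against 62.2%.

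The association of FIE with H3K27me3 differed between the factors. The odds ratio of FIE inside over outside H3K27me3 was 0.436 times as large for AZF1 as for BPC1 regions (normal approximation to the log odds ratios, n = 4464 AZF1 and n = 2622 BPC1 regions, p = 2.41e-12). It was 0.629 times as large on chromosome arms and 0.0598 times without regions in both lists. The approximation treats the lists as independent, although regions in both lists count on both sides. Other signals lay outside the nuclear comparisons: 135 FIE, 115 AZF1 and 97 BPC1 regions on the plastid genome, and 48 AZF1 and 9 H3K27me3 regions on the mitochondrial genome; none was set against a background level of organelle DNA.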

How the results depend on the processing

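No paired analysis was possible because the lists carry no replicate columns, and for the same reason no replicate could be left out. Chromosome arms, gene-matched placements, summit windows, FIE regions up to the median width, gene bodies and strata of gene length were chosen after seeing the data. Of the alternatives computed for the main comparisons, 61 kept the direction and the side of the threshold, 2 passed a threshold newly, 4 reversed and 4 shares moved. All 6 overlaps of lists kept their direction and stayed past the threshold in each of 5 alternatives. The test of H3K27me3 at FIE regions with both factors against neither passed with at least 50% of the region covered (odds ratio 0.501) and with regions cut to 100 bp each side of the summit (0.816), and turned to 1.08 on chromosome arms without passing; the cause was not tested. The difference in median FIE fold turned to -0.271 with at least 50% of the region covered and to -0.291 among FIE regions up to the median width. Wide FIE regions are higher and are less easily covered, which these alternatives alter by construction. The odds ratio of FIE at BPC1 regions with against without AZF1 turned to 0.631 on chromosome arms. BPC1 regions without AZF1 went from 1164 to 791, and those of them at FIE only from 537 to 496. With AZF1 the numbers went from 1458 to 870, and at FIE from 854 to 448. The regions without AZF1 that were left out thus lay mostly away from FIE. The windows left out include the chromosome 2 block with 360 BPC1 regions, whose own part was not tested. Shares of summits (for H3K27me3, region midpoints) in gene bodies moved on chromosome arms, where genes are denser. They were 58.7% for FIE, 69.7% for AZF1, 69.9% for BPC1 and 60.2% for H3K27me3. For AZF1 and BPC1 they lay above the arm shares at shifts of 20000 bp, and for FIE below. Of 26 gene list calls, 20 to 26 were kept across 5 alternatives, which made 20 to 29 calls; in strata of gene length, where tRNA genes were not run, 21 of 22 were kept. The call for tRNA genes in all 4 lists was lost with regions above the median −log10 q and with gene bodies. In 34 single list tests the odds ratio turned without passing. With genes extended by 500 bp these were BPC family in H3K27me3 (0), flowering time in H3K27me3 (1.09), seed storage in AZF1 (1.23) and stress response in H3K27me3 (0.960). With 2 kb they were PRC2-linked in BPC1 (0.820), BPC family in AZF1 (1.04), flowering time in AZF1 (1.04), gibberellin and abscisic acid in all 4 (2.31), photosynthesis in BPC1 (1.498) and ribosomal proteins in AZF1 (1.04). With regions above the median −log10 q they were PRC2-linked in AZF1 (1.55), BPC family in H3K27me3 (0.893), seed storage in AZF1 (2.28), auxin in H3K27me3 (0.932), stress response in H3K27me3 (0.536), photosynthesis in BPC1 (1.38) and H3K27me3 (1.28), and tRNA genes in BPC1 (1.39). In that setting 0 members were left for PRC2 core, BPC family, zinc fingers and ribosomal proteins in BPC1, zinc fingers and gibberellin and abscisic acid in AZF1, and seed storage, stress response and auxin in all 4, of which only the last had been a call. With gene bodies they were PRC2-linked in AZF1 (1.04), BPC family in BPC1 and H3K27me3 (0), gibberellin and abscisic acid in BPC1 (0.989), stress response in H3K27me3 (0.930) and ribosomal proteins in BPC1 (0.494), and in strata of gene length seed storage in AZF1 (1.16). The cause was not tested. Not run were the motif alternatives and the upstream side alone, which need sequence or strand; no rows shared an interval, so taking each row on its own changes nothing.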

Other observations

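The scan of gene families in this part was chosen after the results were seen. Protein-coding genes whose symbols share a letter prefix, in 85 families of at least 15 members, were tested against all other genes for assignment to FIE, AZF1, BPC1 and H3K27me3 (Fisher's exact test, two-sided, adjusted over 340 tests). A shared prefix can join unrelated genes. Families whose prefix is that of transcription factors led the FIE set. Of 67 WRKY genes, a family known from defence and stress responses, 26 were assigned to FIE (38.8% against 9.26% of other genes, Fisher's exact test, adjusted p = 1.48e-08) and 35 to H3K27me3 (Fisher's exact test, adjusted p = 0.000962). Genes with HB symbols, a prefix of homeobox genes, followed with 17 of 37 (Fisher's exact test, adjusted p = 8.47e-07), TCP genes with 9 of 17 (0.000435), NAC genes with 21 of 79 (0.000438), LBD genes with 12 of 35 (0.00172) and MYB genes with 24 of 117 (0.00639). BPC1 was assigned to 9 of the 37 HB genes (Fisher's exact test, adjusted p = 0.00692), 6 of the 17 TCP genes (0.00807) and 17 of the 117 MYB genes (0.0116). No family was assigned to AZF1 more often than other genes past the threshold in these 85 families, and 1 less often, the LCR family of small cysteine-rich proteins with 0 of 80 (Fisher's exact test, adjusted p = 0.0116).

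Genes with CYP symbols, a prefix of cytochrome P450 genes that cyclophilins such as CYP5 share, and a pair of transporter families were among those in the H3K27me3 set. Of 224 genes with CYP symbols, 95 were assigned to H3K27me3 (42.4% against 27.2%, Fisher's exact test, adjusted p = 9.61e-05), and likewise 14 of 23 cation exchanger (CHX) genes (0.0160) and 22 of 42 UMAMIT transporter genes (0.0160). The MYB family had the highest count among transcription factors, with 74 of 117 (63.2%, Fisher's exact test, adjusted p = 1.73e-13). Cell wall genes of the XTH family were assigned to FIE in 9 of 30 cases (Fisher's exact test, adjusted p = 0.0220). BPC1 was assigned to 1 of 160 EMB genes, which are named for embryo defects of their mutants (Fisher's exact test, adjusted p = 0.0214).

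The AZF1 region ranked 2 by fold (5.73; chromosome 5, 26919422 to 26921510) overlapped the AZF1 gene itself, AT5G67450, although its summit lay nearer to AT5G67460, and no FIE, BPC1 or H3K27me3 region overlapped that gene. Its width was 2089 bp, against a median of 144 bp for nuclear AZF1 regions. The plants carried Myc-tagged AZF1, and signal from that copy cannot be told apart from binding at the gene.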
